A study of Mus musculus with 12 samples.

How the data were processed

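Gene expression was measured with 12 two-colour Agilent mouse arrays that compared 6 RNAs. Per the labels, each RNA came from tumour cells of the mouse squamous cell carcinoma NR-S1 that had been cut out by laser microdissection, purified with RNeasy Micro columns and amplified linearly with Agilent's low-input kit. The RNAs were 3 of primary tumours and 3 of lung metastases, where the primary tumour had been left unirradiated, given gamma rays or given carbon ions. Each array held one RNA in Cy3 and another in Cy5, and each pair of RNAs that shared an array was hybridised in both dye orientations, which gave 6 dye swaps of 2 arrays. The unirradiated primary was one of the RNAs on 10 arrays, and the other 2 arrays compared the carbon-irradiated primary with the gamma-irradiated primary. The direction of every ratio was taken from the dyes given in the labels.

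Per the file headers, the arrays were of design 014868 and were scanned and quantified with Agilent Feature Extraction 9.1.3.1 under its protocol GE2-v5_91_0806. The deposited intensity values are the mean pixel brightness of each spot and the median brightness of its local background in each channel, with no normalization. The processed signal intensity in the same deposited files had been corrected for spatial background and normalized between dyes by linear and LOWESS steps, per the file headers. The deposited log10 ratio of each spot is Cy5 over Cy3 of these processed signals, and the deposited p-value of each spot comes from Feature Extraction's error model. The authors' table of values for the series holds log10 values that equalled the scanner files' log ratio within 0.005 in every spot, so scale and direction were known, and the median of each of its 12 columns was 0. Nothing in its centring stayed unknown beyond the steps inside Feature Extraction. Further steps of the authors are not given in the sources used here.

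Every array held 45018 spots, of which 43379 were not controls, and no spot was saturated in either channel. Spots flagged as non-uniform or as population outliers numbered between 16 and 58 per array and were left out. Between 53.8% and 68.8% of spots per channel were well above background, the median signal per channel ran from 93.1 to 147, and the median local background ran from 43 to 62. The slope of observed over nominal log ratios of the spike-in controls was 0.970 to 0.982. The number of arrays and of animals limits the precision.

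Ratios were computed from the mean signals and median backgrounds in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0. The offset pulls ratios of dim spots toward 0. Spots of one probe were averaged, and 245 of the 41174 probes had been printed 10 times. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Probes were named through a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names alone. Of the probes, 22951 matched by accession, 6659 by symbol and 3109 by an older symbol, and 8455 kept the name in the file. This gave 27670 genes or other features, of which 18143 had a name that could be printed. Where a gene had several probes, as 8914 did, the probe with the highest mean log intensity over all arrays stood for it, and another probe's value is given where it lay far from that of the brightest. A gene counted as measured in a comparison where its probe was well above background in at least 1 of the 2 RNAs on every array of the comparison.

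The labels give 1 RNA per group, so the 2 arrays of a dye swap were technical repeats of 1 replicate, no difference had a replicate check, and no p-value across samples was computed. A gene was called higher or lower where its log2 ratio was at least 1 in size, with the same sign, in both dye orientations. Log2 ratios are means over the 2 orientations with their SD, which measures array error and, in direct comparisons, dye error, but not the spread between animals. The background count is the number of genes that passed when the sign of 1 array was left unturned, which a difference between RNAs cannot cause. Metastases were compared with each other through the unirradiated primary, as differences between arrays of the same orientation. A gene's dye effect cancels in these differences, so their SDs and background counts leave it out. The median SD was 0.049 to 0.058 there and 0.107 to 0.129 in direct comparisons. The smaller values do not mean greater precision. That made 9 comparisons, 6 of them direct. The 3 slides held 4 arrays each, and both arrays of every dye swap lay on the same slide. One slide held the unirradiated metastasis and the metastasis after gamma rays, one the metastasis after carbon ions and the primary after gamma rays, and one the primary after carbon ions and the arrays of carbon against gamma.

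Before the data were examined, the comparisons, the size rule, the alternatives, the rule for naming genes and 24 gene lists had been fixed. The lists were p53 targets, interferon response, G2/M and mitosis, DNA replication, DNA repair, hypoxia and glycolysis, keratinocyte, epithelial to mesenchymal transition (EMT) and invasion, chemokines and cytokines, immediate early genes, MHC class I, MHC class II, and markers of lung epithelium, endothelium, skeletal muscle, fibroblasts, smooth muscle, adipocytes, macrophages, neutrophils, T and natural killer cells, B cells, red blood cells and the Y chromosome. Of their 460 genes, 452 were on the array, and the other 8 (Xaf1, Atr, Hspa1b, H2-L, Psme2, Nlrc5, Ly6g and Hbb-b2) had no matching probe name. No gene stood in more than one list, but expression of a marker by several cell types was not excluded. Each list was described by the number of measured members that passed the size rule and by the median log2 ratio, with its percentile among 10000 random lists of the same size matched on mean log intensity in 20 bins and the central 95% range of those lists. Named genes were the 10 highest and 10 lowest of each comparison with the unirradiated primary that passed the size rule, 5 and 5 for the other comparisons, up to 4 members with the largest ratios in each list, and the 10 highest and 10 lowest of the genes shared by the 3 metastases. Features known only by an accession or a clone or model identifier were counted but not named.

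A gene not well above background in one RNA on both arrays was given a lower bound, the brighter RNA's mean against the dimmer RNA's own signal or, where higher, the lowest signal among probes well above background. These bounds were taken from single-channel levels after Aquantile normalization between arrays and are given for RNAs hybridised together. For RNAs compared through the reference, where such a bound could exceed the measured ratio, the measured difference is given and the dim RNA is named. For comparisons that shared the unirradiated primary, 100 simulations with unchanged RNAs against that shared reference gave the correlation, covariance and overlap that sharing alone produces. The calls and list percentiles were tested on simulated data for the dye swap of the gamma-irradiated primary, with 15383 genes. All 50 genes planted at a log2 ratio of 2.5 and all 50 at -2.5 were recovered, as were 49 of 50 at 1.5 and 49 of 50 at -1.5. No call was made among 15183 unchanged genes, whose simulated noise was far smaller than the threshold, so calls were unlikely by design. Of 200 random lists of 20 genes, 8 fell outside the central 95% range. These lists were drawn at random like those they were ranked against, so this checks the calculation alone. It does not show how often lists of genes that vary together fall outside the range.

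Alternatives were Agilent's processed log ratio, the authors' value table, normexp with an offset of 0, median centring without loess, scaling of log ratios between arrays, a filter that required both RNAs above background, no such filter, the mean of all probes of a gene, a further threshold on Agilent's error model p-value of 0.01, the mean of both orientations past the threshold, each orientation alone, a least-squares fit over all 12 arrays with a dye effect per gene, and the same fit with the dye effect of each slide. After the data had been seen, 1 alternative was added that left out the 228 genes of the 14 lists of host tissue, immune and interferon genes.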

Results

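NR-S1 is a highly metastatic squamous cell carcinoma that grows in the hind leg of C3H mice and spreads to the lung. Tumours were left alone or irradiated once they had reached 7.5 mm, with 8 Gy of gamma rays or 5 Gy of carbon ions. Primary tumours were taken 1 week later and lung metastases 2 weeks later, and for the irradiated conditions it was the primary tumour that had been irradiated. Tumour cells were cut out by laser microdissection. There was 1 RNA for each of the 6 conditions, and each of the 6 pairs of RNAs that were hybridised together was measured on 2 arrays with the dyes exchanged. None of the differences below had a replicate check: the error given is the SD over the 2 dye orientations, which leaves out the spread between animals. Ratios are on the log2 scale, with the normexp offset of 50 included, and "rose" and "fell" are used for genes at least 2-fold apart in both orientations. Between 14862 and 17397 genes were measured per comparison.

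**Figure D1:**
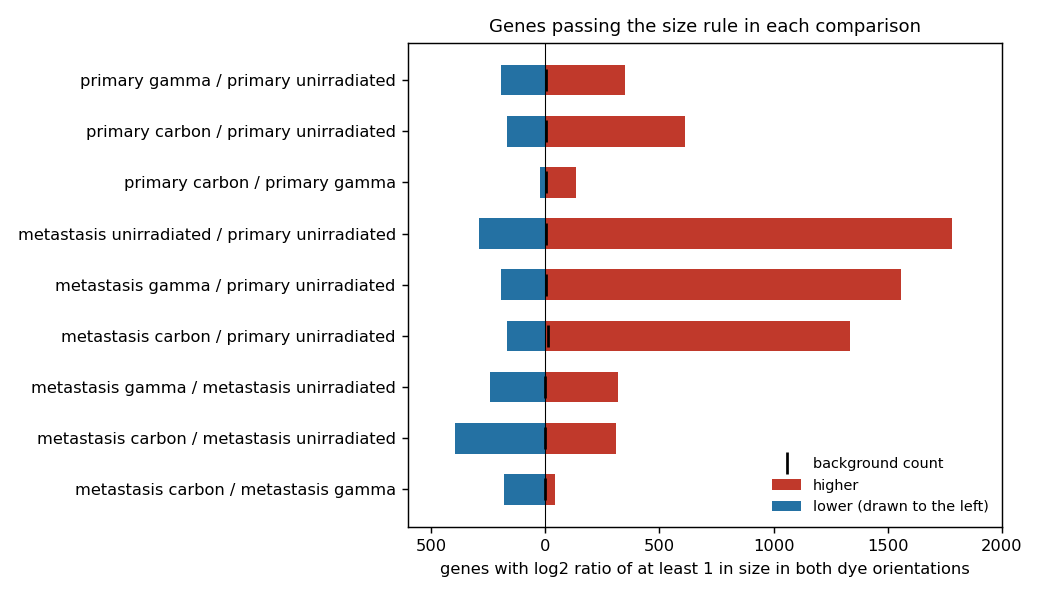
Number of genes (horizontal axis) that passed the size rule in each of the 9 comparisons (vertical axis), with higher genes drawn to the right, lower genes to the left and the background count as a black tick. Counts ran from 157 for the primary after carbon ions over that after gamma rays to 2070 for the unirradiated metastasis, and no background count exceeded 11.

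The first question was how the primary tumour differed 1 week after gamma rays. Interferon-inducible genes led the genes that rose in the gamma-irradiated primary over the unirradiated one. Iigp1, Igtp and Tgtp1, interferon-inducible GTPases of cell-autonomous defence, rose by 4.80 ± 0.05, 4.77 ± 0.05 and 4.79 ± 0.16, the first of these a 27.9-fold difference. A dimmer probe of Tgtp1 gave 1.08. Cxcl9 and Cxcl10, chemokines that attract activated T cells, rose by 4.36 ± 0.02 and 3.56 ± 0.30, and Ifi27l2a, Ifi47 and Rtp4, further interferon-induced genes, by 4.27 ± 0.31, 3.75 ± 0.15 and 3.58 ± 0.22. Wfdc18, which encodes a whey acidic protein domain inhibitor, rose by 4.21 ± 0.16, and Cyp2f2, a cytochrome P450 of airway epithelium, by 4.14 ± 0.25. Among the genes that fell furthest, Sln, a regulator of the muscle calcium pump, fell by 3.62 ± 0.13. Des, the muscle intermediate filament desmin, stood at -2.92 ± 0.09, Actn3 of fast fibres at -2.90, Ankrd1 at -2.70 ± 0.19 and the fast myosin light chain Myl1 at -2.65 ± 0.09, where another Myl1 probe gave -1.36. Tnnt3, a troponin, and Chrna1, the muscle acetylcholine receptor, had ratios of -2.54 and -2.52 ± 0.02, although a second Chrna1 probe gave -0.56. The amino acid transporter Slc7a3 fell to a ratio of -3.54 ± 0.29, the carbonic anhydrase Car6 to -3.26 ± 0.19 and the homeobox gene Rhox5 to -2.58 ± 0.13.

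By group, 23 of 27 measured interferon response genes rose in the gamma-irradiated primary and none fell, with a median of 2.06. Of MHC class I genes, which present antigen on all cells, 10 of 13 rose, with a median of 2.02, and the immunoproteasome subunits Psmb9 and Psmb8 stood at 3.18 ± 0.25 and 3.16 ± 0.24. Of MHC class II genes, typical of antigen-presenting cells, 7 of 10 rose, among them H2-DMb1 at 2.22 ± 0.20 and Cd74 at 2.10 ± 0.02, with a median of 1.75. Markers of T and natural killer cells moved with these groups: 5 of 15 rose, among them Nkg7 at 1.60 ± 0.20 and Il2rb at 1.42 ± 0.07, each well above background in the unirradiated primary on 1 of 2 arrays. The median was 0.96, but 0.24 with both RNAs required above background and 2.77 with Agilent's processed log ratio. Of 22 macrophage markers 1 rose (Arg1, 1.63 ± 0.15), and the median was 0.07. Each of the medians for interferon, MHC and T cell genes lay at percentile 100 of the random lists, whose range for the interferon list was -0.11 to 0.16. Of 23 skeletal muscle markers, 14 fell and none rose, with a median of -1.74 at percentile 0. This list marks muscle of the hind leg around the primary tumour, and the share of such muscle in each dissected RNA was not measured. Hypoxia and glycolysis genes had a median of -0.36 (-0.55 with the gamma RNA in Cy5 alone), and 2 of 24 fell, Ero1a at -2.05 ± 0.08 and Adm at -1.29 ± 0.20. The immediate early list stood at -0.47, with Ier3 at -1.38 ± 0.01, and EMT and invasion genes stood at -0.28, with 2 of 22 lower (Twist2 at -1.22 ± 0.25, and Timp1). Genes of mitosis and of DNA replication had medians of 0.30 and 0.26, above their random ranges, although no member passed the size rule. Endothelial markers stood at -0.38 with 1 of 19 lower (Cldn5, -1.47 ± 0.03), adipocyte markers at -0.57 (-0.17 with no filter on dim probes), smooth muscle markers at -0.26 (-0.41 with the authors' value table) and fibroblast markers at -0.06. In total 348 genes rose and 196 fell, against a background count of 3. With Agilent's processed log ratio the total was 1023, and with median centring in place of loess it was 337.

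Interferon-inducible genes were also highest in the primary tumour after carbon ions. Iigp1 rose by 7.44 ± 0.04, a 174-fold difference, and Igtp by 6.94 ± 0.15, a 122-fold difference. Tgtp1 rose by 5.71 ± 0.24 (2.98 with its dimmer probe), Cxcl10 by 5.52 ± 0.31, the guanylate-binding protein Gbp3 by 5.52 ± 0.02, Ifi47 by 5.25 ± 0.07, Ifi27l2a by 5.19 ± 0.38, Cxcl9 by 5.16 ± 0.13, Rtp4 by 4.98 ± 0.16 and the epidermal lipoxygenase Alox12e by 4.84 ± 0.25. Among the genes that fell were Slc7a3 and Car6 once more, with ratios of -3.43 ± 0.01 and -3.12 ± 0.17, and Rhox5, which fell 12.3-fold. Ambp, an inhibitor of proteases, fell 5.66-fold, the chromatin protein Hmga2 to a ratio of -2.46 ± 0.26 and the myosin heavy chain Myh2 to -2.34 ± 0.29. The galectin Lgals1 stood at -2.25 ± 0.52, the keratin Krt23 at -2.17 ± 0.09, Fam160a1 at -2.21 ± 0.02 and Rap1gap, which inactivates the GTPase Rap1, at -2.12 ± 0.25. Other probes of Hmga2 gave -2.18 and -0.36 and one of Rap1gap gave -0.78, and Lgals1 no longer passed with median centring.

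Of 27 interferon response genes, 26 rose in the carbon-irradiated primary, with a median of 2.95. MHC class I genes rose in 12 of 13 cases with a median of 2.58, and MHC class II genes in 8 of 10 with a median of 2.82, among them the class II activator Ciita at 3.08 ± 0.14. Of T and natural killer cell markers 8 of 16 rose, among them Il2rb at 2.43 ± 0.13, well above background in the unirradiated primary on 1 of 2 arrays, and Nkg7 at 2.40 ± 0.07. The cytokine Ifng was not well above background in the unirradiated primary and was at least 5.18-fold higher. The list's median was 1.25, and 2.89 with Agilent's processed log ratio. Macrophage markers had a median of 0.14 and none of 21 passed. Neutrophil markers stood at -0.98 (-0.40 with no filter on dim probes): 3 of 10 fell, S100a8 at -1.65 ± 0.06, S100a9 at -1.41 ± 0.38 and Csf3r at -1.37 ± 0.08, while Ltf rose by 1.89 ± 0.01. Skeletal muscle markers had a median of -0.72 with 5 of 23 lower. Genes of mitosis, replication and repair had medians of -0.30, -0.24 and -0.21, below their random ranges, with no member past the size rule, and the repair median was -0.12 and -0.36 in the separate orientations. Of p53 targets, which respond to DNA damage, Sesn1 rose by 1.36 ± 0.11 and Trp53inp1 by 1.28 ± 0.04 while Gadd45a fell by 1.30 ± 0.06, and the list's median of 0.19 lay inside its random range. Keratinocyte genes, those of the tumour's own lineage, stood at 0.02, and 3 of 25 fell: Krt16 (-1.51 ± 0.35), Krt19 (-1.45) and Sprr1b (-1.36 ± 0.07). Among chemokines and cytokines 3 of 22 rose and 3 fell, with Cxcl1 at -1.87 ± 0.25. B cell markers, of which 3 were measured, stood at -0.02 (-0.57 with both RNAs above background) and red blood cell markers at 0.42 (0.028 with no filter on dim probes). In total 611 genes rose and 168 fell, against a background count of 4. Agilent's processed log ratio gave 1393 genes and median centring 473.

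Both irradiated primaries were compared with the same unirradiated RNA. Their ratios correlated across 14642 genes with r = 0.859 (Spearman 0.794), and genes are not independent replicates. Unchanged RNAs that shared the reference gave 0.417 in simulation, and the covariance was 0.236 against a simulated 0.0484. In both, 320 genes rose and 95 fell, none in opposite directions, where independent lists would share 14.0 and 2.19. Part of the excess may come from the shared control, a single RNA that could not be split, and the simulation took the difference between the irradiated primaries as the spread of unchanged RNAs.

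**Figure D2:**
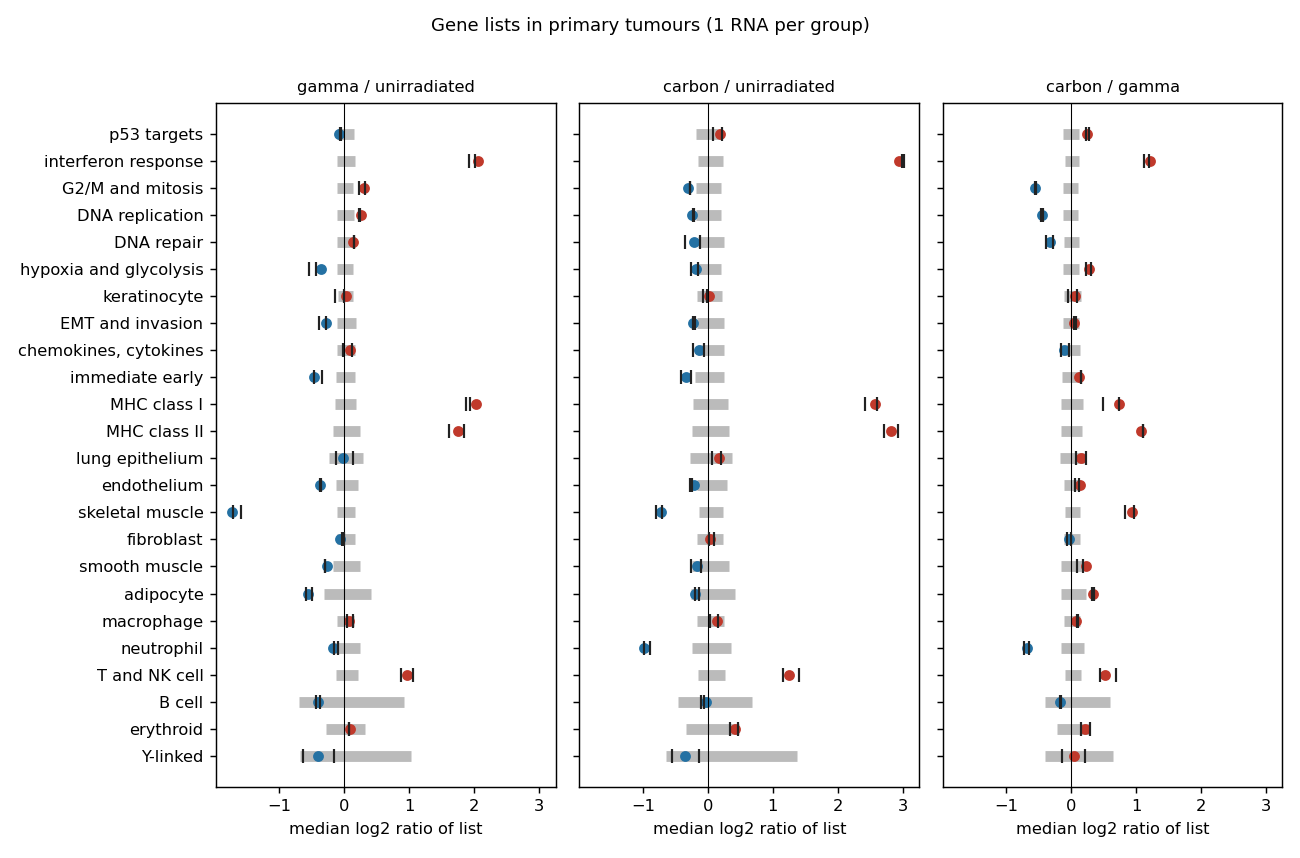
Median log2 ratio (horizontal axis) of each of the 24 gene lists (vertical axis) in the primary tumours after gamma rays, after carbon ions, and after carbon ions over gamma rays. Points are medians over the measured members, ticks the medians in each dye orientation and grey bars the central 95% range of random lists, and the interferon list stood at 2.06, 2.95 and 1.21.

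Whether the radiation types differed in the primary tumour was measured on arrays that held both irradiated RNAs. Iigp1 and Igtp were higher again after carbon ions, by 3.06 ± 0.14 and 2.95 ± 0.04, an 8.34-fold and a 7.75-fold difference. Apol10a and Apol6, apolipoprotein L genes that interferon induces, rose by 2.91 ± 0.10 and 2.90 ± 0.06, and the guanylate-binding protein Gbp8 by 2.87 ± 0.09. The epidermal envelope protein genes Cnfn and Crct1 were lower after carbon ions, at -2.42 ± 0.03 and -1.58 ± 0.06, as were the stefin Cstdc6 at -1.54 and the calprotectin genes S100a9 and S100a8 at -1.52 ± 0.31 and -1.49 ± 0.06. The calls for S100a9 and S100a8 were lost with median centring. Of 27 interferon response genes 15 rose, with a median of 1.21 and Cxcl10 at 2.06 ± 0.22. Of MHC class II genes 5 of 10 rose (median 1.07, Ciita 1.76 ± 0.31), while no MHC class I gene passed, at a median of 0.74 that was 0.48 with carbon in Cy3 alone. T and natural killer cell markers stood at 0.52 (0.84 with the authors' value table), with Ifng and Il2rb higher at 1.32 ± 0.18 and 1.11 ± 0.02. Of 21 skeletal muscle markers 9 rose, with a median of 0.93, Actn3 at 2.02 ± 0.02 and Myl1 at 1.83 ± 0.09. Genes of mitosis (-0.55), replication (-0.45) and repair (-0.32) had medians below their random ranges, and no member passed. The p53 targets stood at 0.24, above their random range of -0.12 to 0.11, with none of 24 past the rule, and neutrophil markers stood at -0.69. In total 133 genes rose and 24 fell, against a background count of 1. That total was 73 with median centring, 328 with Agilent's processed log ratio, 262 with scaling between arrays, 248 with an offset of 0 and 257 on the arrays with carbon in Cy5 alone. The same difference taken through the unirradiated primary correlated with the direct one at r = 0.977 across 14642 genes, and the 2 measurements differed with an SD of 0.0667.

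The metastases were compared with the unirradiated primary to ask what distinguished tumour cells in the lung. In the unirradiated metastasis Sftpd, a surfactant protein, rose by 7.63 ± 0.41, a 199-fold difference, Sec14l3, an airway lipid carrier, by 6.34 ± 0.04 (1.85 to 3.49 with other probes), and Hc, complement component C5, by 6.31 ± 0.13. Chil4 and Chil3, chitinase-like proteins of macrophages and airways, rose by 6.15 ± 0.02 and 5.83 ± 0.21, the eosinophil-type ribonuclease Rnase2a by 5.84 ± 0.10, the endothelial receptor Calcrl by 5.84 ± 0.03 (0.98 with another probe), S100a8 by 5.70 ± 0.27 and Iigp1 by 6.11 ± 0.50. S100g, a calcium-binding protein, was at least 57.7-fold higher, since it was not well above background in the unirradiated primary. Among the lowest genes Myl1 fell by 5.41 ± 0.23, with another probe at -1.76, Myh8 stood at -4.40 ± 0.38, Tnnt3 at -4.15, Myh4 at -4.05 ± 0.49 and Tnnc2 at -3.88 ± 0.20, and Actn3 was 16.0-fold lower. Adm (adrenomedullin), Egln3 (a prolyl hydroxylase that hypoxia induces) and Mgarp (a mitochondrial protein) stood at -4.70 ± 0.23, -3.90 ± 0.04 and -4.44 ± 0.02, and Lrrc15 at -3.87 ± 0.03 with a second probe at -1.18.

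In the unirradiated metastasis 17 of 20 lung epithelial markers rose, with a median of 3.95, and markers of other cell types were higher beside them. Those that rose were 18 of 20 for endothelium (median 1.87, Vwf 4.23 ± 0.20), 20 of 22 for macrophages (1.77, Marco 5.38 ± 0.21), 12 of 13 for neutrophils (3.24, Retnlg 5.18 ± 0.05), 12 of 18 for T and natural killer cells (1.87, Cd3g 3.30 ± 0.15, above background in the primary on 1 of 2 arrays) and 3 of 6 for red blood cells (1.52, Hbb-bt 4.34 ± 0.02). The red blood cell median was 0.47 with no filter on dim probes. Of 27 interferon response genes all rose, with a median of 2.93, as did 12 of 13 MHC class I genes (1.88), 10 of 10 MHC class II genes (2.60) and 14 of 25 chemokines and cytokines (1.34). The chemokine median was 2.29 and that of T and natural killer cell markers 3.13 with Agilent's processed log ratio. Of 24 hypoxia and glycolysis genes 16 fell and none rose, with a median of -1.54, among them Bnip3 at -3.75 ± 0.34 and Ero1a at -3.74 ± 0.07. Skeletal muscle markers fell in 17 of 23 cases with a median of -2.43, which was -3.95 with the authors' value table and -1.62 with the mean of all probes. How much leg muscle the RNA of the unirradiated primary held was not measured. Fibroblast markers had a median of 0.34 (0.087 with median centring) with 7 of 23 higher and 1 lower, smooth muscle markers -0.20, and keratinocyte genes -0.14 with 1 of 23 past the rule (Sprr1a, 1.85 ± 0.01). In total 1781 genes rose and 289 fell, against a background count of 1, and Agilent's processed log ratio gave 3237 genes.

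In the metastasis after gamma rays the secretoglobin Scgb3a2 of airway cells rose by 8.25 ± 0.08 over the unirradiated primary, a 305-fold difference, followed by Sftpd at 7.52 ± 0.27, Hc at 6.41 ± 0.06 and Sec14l3 at 6.21 ± 0.05. The lymphoid chemokine Ccl19 rose by 5.66 ± 0.26, the antimicrobial lectin Reg3g by 5.64, the club cell secretoglobin Scgb1a1 by 5.63 ± 0.16, the macrophage scavenger receptor Marco by 5.58 ± 0.06, the tetraspanin Tspan1 by 5.51 ± 0.03 and the B cell surface gene Ms4a1 by 5.46 ± 0.28, which was well above background in the unirradiated primary on 1 of 2 arrays. The muscle gene Myl1 stood at -4.96 ± 0.19, Tnnt3 at -4.15 ± 0.05, Actn3 at -4.11 ± 0.15 and Acta1 at -3.76 ± 0.25. Of 20 lung epithelial markers 18 rose (median 4.06), as did 9 of 12 B cell markers (2.33, and 3.90 with Agilent's processed log ratio), 13 of 20 endothelial markers (1.46), 9 of 21 macrophage markers (0.98, and 0.61 with median centring) and 11 of 13 neutrophil markers (2.15). Of interferon response genes 27 of 27 rose, at a median of 2.30, and 9 of 24 hypoxia genes fell, at a median of -0.72 that was -1.20 with median centring. In total 1558 genes rose and 195 fell, against a background count of 1. The total was 3375 with Agilent's processed log ratio and 2666 with an offset of 0.

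In the metastasis after carbon ions Scgb3a2 rose by 8.07 ± 0.11, a 269-fold difference, Sftpd by 7.45 ± 0.33, Hc by 6.67 ± 0.03, Sec14l3 by 6.46 ± 0.06, Scgb1a1 by 5.73 ± 0.30, Tspan1 by 5.52 ± 0.01, Iigp1 by 5.08 ± 0.05, Sec14l4 by 5.04 ± 0.07 and the surfactant gene Sftpc by 5.03 ± 1.18. S100g was at least 46.8-fold higher. Myl1, Tnnt3 and Myh8 had the lowest ratios at -5.29 ± 0.17, -4.19 ± 0.10 and -4.10 ± 0.40, and the matrix protein gene Thbs4, well above background in the metastasis on 1 of 2 arrays, fell by 3.79 ± 0.03. Lung epithelial markers rose in 18 of 20 cases (median 4.18), endothelial markers in 13 of 20 (1.67), macrophage markers in 8 of 22 (0.87), neutrophil markers in 4 of 13 (0.56, and 0.90 with the authors' value table) and interferon response genes in 26 of 27 (2.33). Of 24 hypoxia and glycolysis genes 3 fell, at a median of -0.36 that was -0.69 with median centring. Among immediate early and stress genes the heat shock gene Hspa1a rose by 2.46 ± 0.09, Atf3 by 1.26 ± 0.12 and the matricellular gene Ccn2 also rose, while Ier3 fell by 1.57 ± 0.07, and the median was 0.32 but -0.06 with median centring. In total 1336 genes rose and 168 fell, against a background count of 11, and Agilent's processed log ratio gave 2614 genes.

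**Figure D3:**
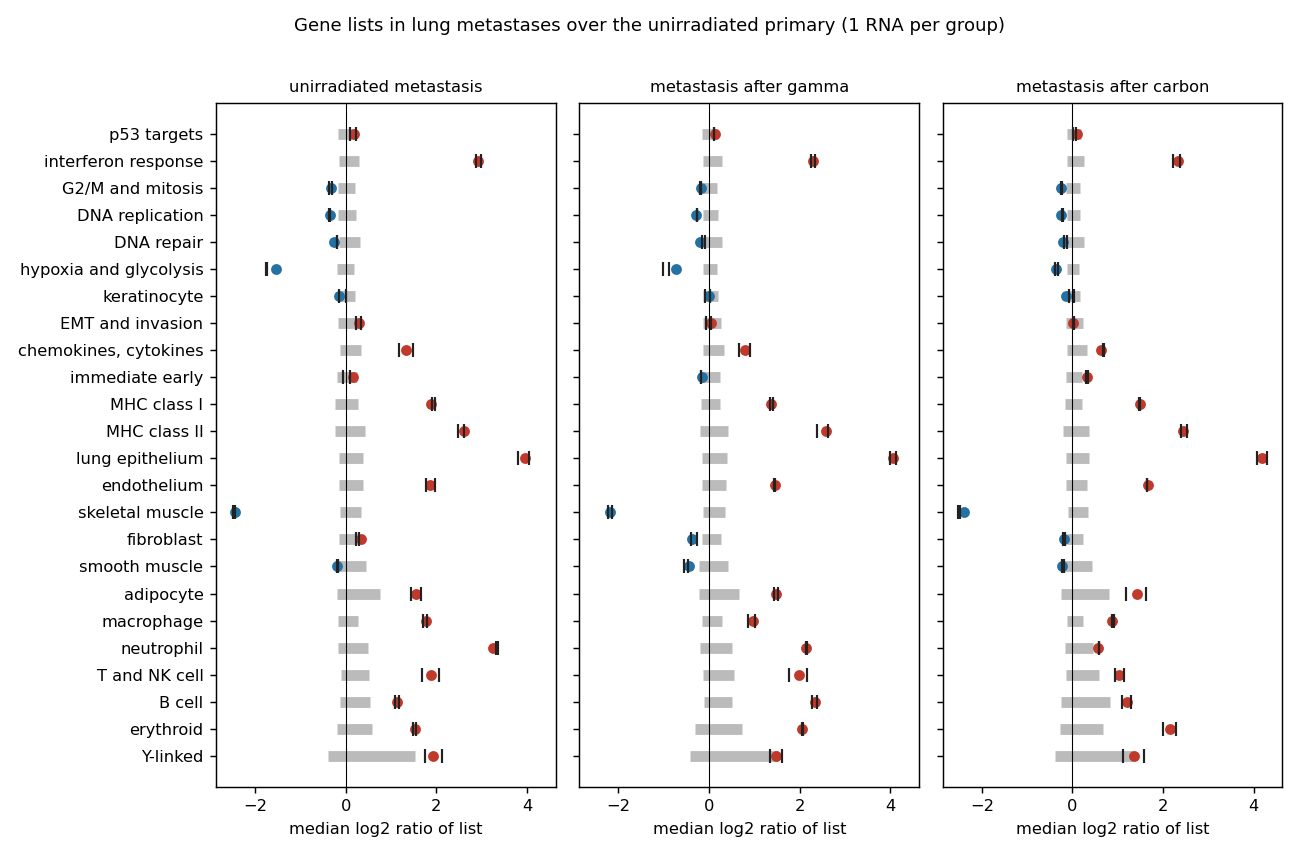
Median log2 ratio over the unirradiated primary (horizontal axis) of each of the 24 gene lists (vertical axis) in the unirradiated metastasis and in the metastases after gamma rays and after carbon ions. Points are medians over the measured members, ticks the medians in each dye orientation and grey bars the central 95% range of random lists, and lung epithelium stood at 3.95, 4.06 and 4.18 while skeletal muscle stood at -2.43, -2.18 and -2.40.

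The metastases had many genes in common relative to the primary. Of 15762 genes measured in all 3 comparisons, 928 rose in every one and 102 fell in every one, 1030 in total. The highest shared genes by their smallest ratio were Sftpd, Hc, Sec14l3, S100g, the surfactant genes Sftpa1 and Sftpc, Scgb1a1, Sec14l4, Rnase2a and Iigp1, and the lowest were Myl1, Tnnt3, Myh8, Myh4, Actn3, Tnnc2, Lrrc15, Chrna1, Acta1 and Myh1. Sftpa1 stood at 5.04 ± 0.70, 5.02 ± 0.55 and 4.96 ± 0.55 in the unirradiated, gamma and carbon metastases, and Acta1 at -3.68 ± 0.26, -3.76 ± 0.25 and -3.57 ± 0.27. Independent lists of these sizes would share 13.7 higher and 0.0379 lower genes, and simulated unchanged RNAs against the shared reference shared 31.8 and 31.7 on average. The pairwise correlations across genes were 0.858, 0.809 and 0.902 where simulation gave 0.450, 0.440 and 0.440, and the covariances were 0.489, 0.432 and 0.422 where it gave 0.0863, 0.0861 and 0.0862. The single reference RNA could not be split, so part of the excess may come from it. The count was 1672 with Agilent's processed log ratio and 654 with median centring.

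Differences among the metastases were taken through the unirradiated primary. Dye effects of a gene cancel there, so SDs and background counts cannot be set beside those of direct comparisons. After gamma rays, Reg3g and Glycam1, a mucin-like ligand of lymph node vessels, were higher than in the unirradiated metastasis, where they were not well above background, with measured log2 differences of 5.65 ± 0.12 and 4.46 ± 0.30. Bpifa1 and Scgb3a2, expressed in airways, rose by 4.24 ± 0.26 and 4.14 ± 0.04, and Ccl19 by 3.83 ± 0.14. Chil3, the tryptophan-degrading enzyme gene Ido1, the stefin genes Csta2 and Stfa2, and Chil4 fell, with values of -3.42 ± 0.31, -3.18 ± 0.03, -3.17 ± 0.06, -3.01 ± 0.02 and -2.99 ± 0.09. Of 24 hypoxia and glycolysis genes 11 rose and 1 fell, with a median of 0.86, Adm at 3.17 ± 0.02 and Egln3 at 2.66 ± 0.01. Of 12 B cell markers 7 rose (median 1.30, Ms4a1 2.36 ± 0.16, and Cr2 2.46 ± 0.29, above background in the unirradiated metastasis on 1 of 2 arrays). Neutrophil markers fell in 8 of 13 cases and rose in 1 (median -1.69, S100a8 -2.24 ± 0.21), macrophage markers in 7 of 21 (-0.82, Adgre1 -1.25 ± 0.03), fibroblast markers in 6 of 23 (-0.66) and chemokines and cytokines in 5 of 25 (-0.54). Endothelial markers stood at -0.55 with none past the rule. Interferon response genes had a median of -0.42 (-0.64 with scaling between arrays) with 4 of 27 lower, among them Cxcl10 at -2.29 ± 0.04, and MHC class I genes a median of -0.55 with none past the rule. Lung epithelial markers had a median of -0.05, with 4 higher and 1 lower, and red blood cell markers stood at -0.18. T and natural killer cell markers stood at 0.08, with Lck and Cd5 higher at 1.29 ± 0.12 and 1.28 ± 0.13 and Ifng lower at -2.20 ± 0.06. The unirradiated and gamma metastases were on the same slide, and 320 genes rose and 243 fell, against a background count of 0. The majority turned to lower genes with median centring (253 and 291) and with scaling between arrays (214 and 270). The total was 1506 with Agilent's processed log ratio and 993 with an offset of 0.

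After carbon ions, neutrophil genes were lower than in the unirradiated metastasis. S100a8, S100a9 and Retnlg, abundant genes of neutrophils, stood at -5.42 ± 0.18, -4.81 ± 1.09 and -4.61 ± 0.02, and the stefin genes Stfa2l1 and Csta2 at -5.16 ± 0.13 and -4.75 ± 0.10. Scgb3a2 rose by 3.96 ± 0.07, Adm by 3.63 ± 0.09, Mgarp by 3.57 ± 0.22, Lrrc23, a gene of motile cilia, by 3.47 ± 0.15 and the amine oxidase Aoc1 by 3.39 ± 0.03. Of 24 hypoxia and glycolysis genes 17 rose and 1 fell, with a median of 1.40, Bnip3 at 3.07 ± 0.15 and Ndrg1 at 3.04 ± 0.03. Neutrophil markers fell in 10 of 13 cases and rose in 1, with a median of -2.91, and macrophage markers in 7 of 22 with a median of -0.95. Interferon response genes stood at -0.43 with 3 of 27 lower, MHC class I genes at -0.53 with none lower, and T and natural killer cell markers at -0.43 with 2 of 18 lower, Ifng among them at -1.85 ± 0.08. Endothelial markers stood at -0.47, fibroblast markers at -0.48, adipocyte markers at -0.57 (-0.93 with the authors' value table and -0.25 with no filter on dim probes), red blood cell markers at -0.21, and lung epithelial markers at 0.15, which turned to -0.12 with scaling between arrays. These RNAs were measured on different slides, so slide and treatment cannot be told apart. In total 309 genes rose and 397 fell, against a background count of 0. The total was 1547 with Agilent's processed log ratio, of which 824 were higher and 723 lower, so that the majority turned, and it was 1087 with an offset of 0.

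Between the metastases after carbon ions and after gamma rays, the heat shock gene Hspa1a was 5.32-fold higher after carbon ions, a log2 difference of 2.41 ± 0.08. Mid1, a microtubule-associated ubiquitin ligase gene, rose by 2.15 ± 0.28, the potassium channel gene Kcna7 by 2.12 ± 0.32, and Olfr430 and Krtap17-1 by 2.05 ± 0.01 and 2.02 ± 0.02. Glycam1 fell by 4.44 ± 0.37 and was well above background after carbon ions on 1 of 2 arrays, Sprr2f, a small proline-rich protein of epithelia, fell by 4.05 ± 0.09, and the adipokine gene Cfd stood at -4.03 ± 0.22, Reg3g at -3.79 ± 0.02 and Ms4a1 at -3.75 ± 0.14. B cell markers fell in 8 of 12 cases, with a median of -1.81, neutrophil markers in 5 of 13 (-0.94), T and natural killer cell markers in 4 of 19 (-0.50, and -0.32 with Agilent's processed log ratio) and adipocyte markers in 4 of 9 (-0.81, but -1.25 with an offset of 0 and -0.32 with both RNAs above background). Immediate early genes rose in 5 of 19 cases, with a median of 0.59, Atf3 at 1.32 ± 0.04 and Fos at 1.23 ± 0.05. Hypoxia and glycolysis genes stood at 0.41 with 3 of 24 higher, and interferon response genes at 0.12 with none past the rule. These RNAs were on different slides too, and slide and treatment cannot be told apart. In total 41 genes rose and 183 fell, against a background count of 0. The total was 593 with Agilent's processed log ratio, 359 with an offset of 0 and 149 with scaling between arrays, and Krtap17-1 was lost with Agilent's ratio.

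**Figure D4:**
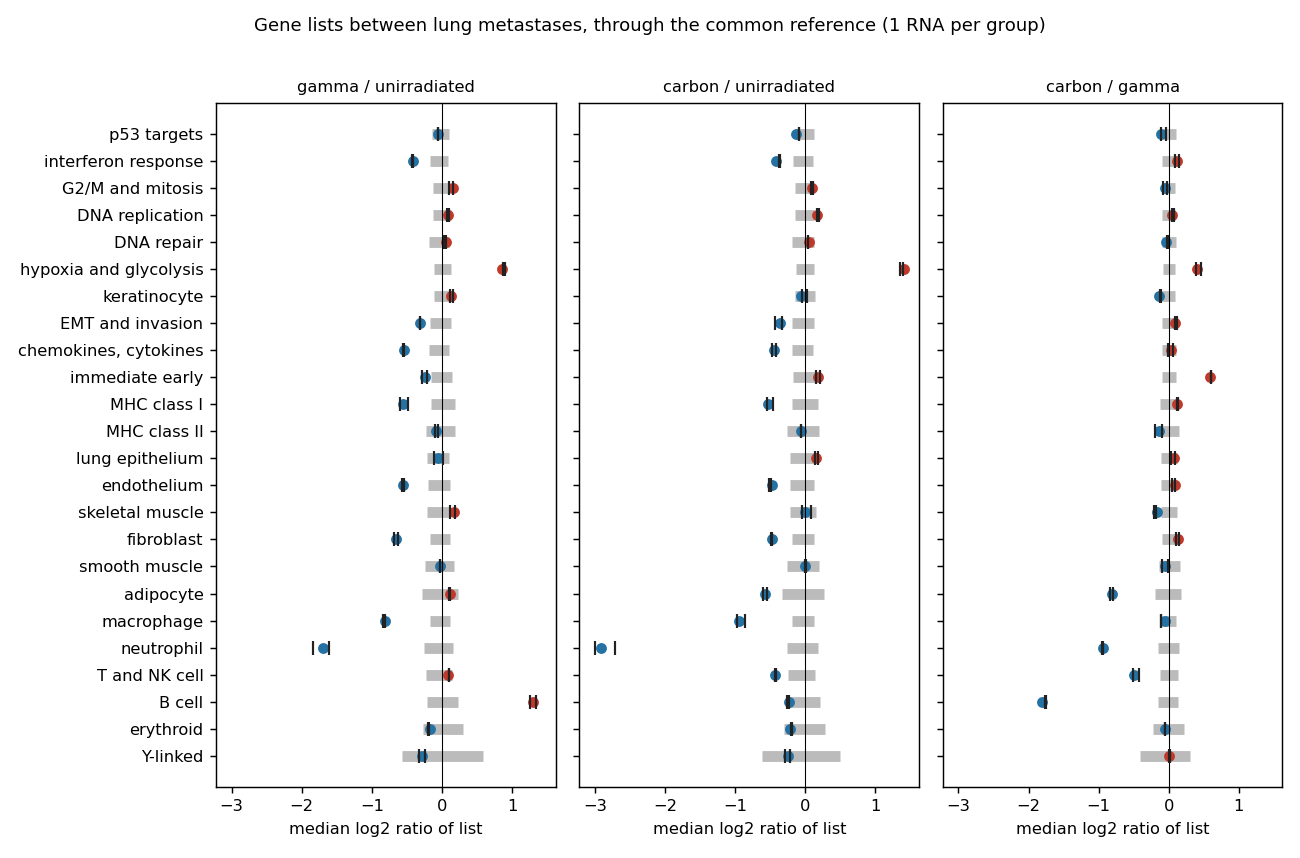
Median log2 difference between lung metastases (horizontal axis) of each of the 24 gene lists (vertical axis): gamma over unirradiated, carbon over unirradiated and carbon over gamma. Points are medians over the measured members, ticks the medians in each dye orientation and grey bars the central 95% range of random lists, and neutrophil genes stood at -1.69, -2.91 and -0.94 while hypoxia genes stood at 0.86, 1.40 and 0.41.

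Whether the radiation types left a larger difference in primaries or in metastases was compared through the same reference over 14642 genes measured on all arrays concerned. The carbon minus gamma ratios had an SD over genes of 0.304 in primaries and 0.305 in metastases, a ratio of 1.01 that was 1.07 and 0.964 in the separate orientations. Of the same genes, 127 were higher and 29 lower after carbon ions in primaries, and 38 were higher and 112 lower in metastases. The highest list median after carbon over gamma in primaries was that of interferon genes, and the lowest in metastases were those of B cell and neutrophil genes. The ratio over the unirradiated sample of the same site correlated across genes between metastasis and primary at r = 0.192 (Spearman 0.302) for gamma rays and 0.171 (Spearman 0.241) for carbon ions, with genes not independent replicates. With scaling between arrays these were 0.0971 and 0.109. The interferon list, at 2.06 and 2.95 in the irradiated primaries, stood at -0.42 and -0.43 in the corresponding metastases.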

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

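Of the tests below, that on white blood cell genes was set before their values were seen, and all others were chosen only after the result was seen. The difference by treatment was set side by side in primaries and metastases for 24 lists under 3 contrasts, 72 in all. Of these, 14 went opposite ways in both dye orientations, outside the random range at both sites. Those that went the same way were not counted. Over all comparisons 140 of 216 list medians lay outside their random range, so opposite pairs can also arise between unrelated medians. There was 1 RNA per group, so none of these differences was tested. Besides the site, primaries and metastases differed in time (1 week and 2 weeks), and only the primary tumour had been irradiated. Contrasts that held the metastasis after carbon ions also crossed slides. For gamma rays over no irradiation, the median in metastases minus that in primaries was -2.48 for interferon response, -2.57 for MHC class I, 1.91 for skeletal muscle and 1.22 for hypoxia and glycolysis genes. For carbon ions over no irradiation it was -3.38 for interferon response, -3.11 for MHC class I, -1.68 for T and natural killer cell, 0.41 for DNA replication and 0.51 for immediate early genes. For carbon ions over gamma rays it was -1.22 for MHC class II, -1.09 for skeletal muscle, -1.15 for adipocyte, -1.02 for T and natural killer cell genes and -0.36 for p53 targets. None of the medians behind these values changed sign under an alternative, but several metastasis medians came near 0. For gamma rays over no irradiation, skeletal muscle went from 0.17 to 0.057 with no filter on dim probes. For carbon ions over no irradiation, DNA replication went from 0.17 to 0.015 and immediate early genes from 0.18 to 0.037 with median centring. For carbon ions over gamma rays, p53 targets went from -0.11 to -0.040 with the metastasis RNAs in Cy3 alone, MHC class II from -0.14 to -0.059 with median centring, skeletal muscle from -0.16 to -0.049 with the mean of all probes, and adipocyte genes from -0.81 to -0.32 with both RNAs above background.

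Interferon genes were higher in irradiated primaries, and higher after carbon than after gamma. White blood cells in the dissected tissue would bring their general genes. The upper quartile of 12 such genes reached only 0.48, against a lower quartile of 1.52 for interferon genes. This argues against a larger share of white blood cells in general as the whole source. It cannot decide on a change in their types or activity. T and natural killer cell markers were higher in both irradiated primaries, with a median of 1.25 after carbon ions, while macrophage markers hardly moved. An unirradiated primary that was itself low in interferon genes cannot be told apart from a response to irradiation: all 5 other RNAs lay above it by 2.06 or more, the unirradiated metastasis included. That reference cannot account for carbon above gamma, since arrays without it gave 1.21 where the random range ended at 0.12. An interferon response to irradiation that was larger after carbon ions may be the source. It stays untested with 1 RNA per group, as does a difference between the animals sampled.

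Neutrophil genes were lower and hypoxia genes higher in metastases after irradiation. Beside them, after gamma rays and carbon ions, medians were -0.82 and -0.95 for macrophage, -0.28 and -1.11 for general white blood cell, -0.66 and -0.48 for fibroblast and -0.55 and -0.47 for endothelial genes, while B cell genes stood at 1.30 and -0.23. Less blood would have lowered red blood cell genes as well. Their medians were lower in both metastases, but by less: the lower quartile was -0.34 against neutrophil medians of -1.69 and -2.91. Less blood as part of the source therefore stays open. Less lung tissue would have lowered lung genes, whose lower quartile was -0.16. A list of 11 further lung genes had lower quartiles of -0.55 and -0.50, with medians of -0.05 and 0.05. Lung genes went both ways, such as Scgb3a2 at 4.14 and Hopx at -0.54 after gamma rays. A loss of part of the lung tissue therefore stays open. Slides were not the source after gamma rays, since the hypoxia list stood at 0.86 between arrays of the same slide. After carbon ions slide and treatment cannot be told apart. The hypoxia list differed by 0.0368 between measurements of 1 pair of primary RNAs on different slides. The slide of the unirradiated metastasis was not among these, so that value cannot decide the question. The differences after gamma rays and after carbon ions were taken from the same unirradiated metastasis RNA, so they are not independent of each other. An unirradiated metastasis that was itself high in neutrophil genes and low in hypoxia genes cannot be told apart from a response to irradiation. A smaller share of neutrophils, alone or with some other cell types, and poorer oxygen supply after irradiation could be the source. Differences in size or place between the metastases sampled could be as well, and neither was tested.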

How the results depend on the processing

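No paired analysis was possible because every group had replicate number 1 only. Under 14 alternatives and 1 added after seeing the data, no gene that passed the size rule passed it in the opposite direction. Of the values for 157 named genes under alternatives, 2271 stayed past the rule and 15 did not, 10 of them under the error model threshold. A further 69 were not given: 10 where both RNAs had to be above background and 59 where host list genes were left out. Many of the 2271 were fixed in advance. Named genes had passed in both orientations, so each orientation alone, their mean and no filter could lose none. Requiring both RNAs above background or leaving out host genes could only keep a value or give none. Of those for 216 list medians, 1611 moved by less than the technical SD, 976 by more and 5 reversed. A reversal was counted only for medians outside their random range with the same sign in both orientations, so other medians near 0 could change sign uncounted. Those reversed included immediate early genes in the carbon metastasis with median centring (-0.0646) and adipocyte genes there with no filter (-0.0127). The others were mitosis (-0.0472) and keratinocyte genes (-0.0730) in the gamma metastasis over the unirradiated one with median centring, and lung genes in the carbon metastasis over the unirradiated one with scaling (-0.12). Of 140 medians outside their random range, 70 moved by over 1.5 times under at least 1 alternative. The interferon median stayed between 1.85 and 2.34 in the gamma primary and between 2.72 and 3.24 in the carbon primary. Less stable were T and natural killer cell genes in these primaries (0.24 to 2.77 and 0.87 to 2.89), neutrophil genes in the carbon primary (-1.33 to -0.40), hypoxia genes in the gamma metastasis (-1.20 to -0.60), adipocyte genes in the carbon over the gamma metastasis (-1.25 to -0.32), skeletal muscle genes in the unirradiated, gamma and carbon metastases (-3.95 to -1.62, -4.15 to -1.63 and -3.97 to -1.64) and red blood cell genes in the unirradiated, gamma and carbon metastases (0.47 to 2.81, 0.23 to 2.54 and 0.093 to 3.02), which were lowest with no filter on dim probes. Leaving out host list genes changed no count by over 1.5 times. Only the 228 listed genes were removed and other genes of host cells stayed, so this does not measure the part of host tissue. The cause of the shifts below was not tested unless stated.

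With Agilent's processed log ratio, counts in the order of the report were 1023, 1393, 328, 3237, 3375, 2614, 1506, 1547 and 593, with 1672 shared by the metastases, a summed background of 74 and a closure correlation (direct against indirect carbon over gamma) of 0.950. The authors' value table gave 1020, 1390, 328, 3232, 3366, 2609, 1504, 1544 and 592, with 1670 shared, a background of 72 and a closure of 0.950. These ratios carry no offset, and dim genes count in full. Median centring gave 337, 473 and 73 in primaries, 654 shared and a background of 1004 against 21. An offset of 0 gave 248 for carbon over gamma, 2666 for the gamma metastasis, 993, 1087 and 359 between metastases, and a closure of 0.958. Scaling gave 262 for carbon over gamma and 149 between those metastases, a spread ratio of 0.830, a closure of 0.955, and 0.0971 and 0.109 for the responses of metastasis against primary to gamma rays and carbon ions. The error model threshold removed no gene from the direct comparisons. Between metastases it left 301, 329 and 131, but its p-value sets each metastasis against the unirradiated primary, so a gene at the level of the primary in either metastasis fails by construction, and these counts say nothing about the differences. With no filter the spread ratio was 1.13 and closure 0.915, with both RNAs above background closure was 0.978, and with the mean of all probes 0.974. With 1 orientation at a time, carbon over gamma counted 206 to 257, closure was 0.888 to 0.890 and the gamma response correlation 0.169 to 0.201. Closure under the fits over all arrays is fixed by their construction and was not given, nor was the background count under settings without an unturned array.

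The split of higher against lower calls moved by over 10 points in these cases. Agilent's ratio gave 939 and 454 for the carbon primary (main 611 and 168), 235 and 93 for carbon over gamma (133 and 24), 2363 and 874 for the unirradiated metastasis (1781 and 289), 2595 and 780 for the gamma metastasis (1558 and 195) and 1007 and 499 for the gamma over the unirradiated metastasis (320 and 243), and the value table gave nearly the same. The last split was 253 and 291 with median centring and 214 and 270 with scaling. Splits under the error model (127 and 174, and 92 and 237 for carbon over unirradiated metastasis, main 309 and 397) are set by the same construction. With other settings carbon over unirradiated metastasis moved by less, but its majority turned to higher genes with Agilent's ratio (824 and 723) and the value table (824 and 720). The median of all genes shifted by -0.16, -0.10 and -0.10 in the 3 metastases with Agilent's ratio, and by -0.18 and -0.17 in the gamma and carbon metastases with median centring. As few as 53.8% of spots per channel were well above background.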

Other observations

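Of the tests below, that on added lung genes was set before their values were seen, and the others were chosen only after the result was seen. General white blood cell genes, a list of 12 added after the data were first examined, differed among the metastases. All 12 rose over the unirradiated primary in the unirradiated metastasis and in that after gamma rays, with medians of 2.32 and 2.23, and 7 rose after carbon ions, with a median of 1.32. Ptprc, the common leukocyte antigen, stood at 2.97 ± 0.23, 2.67 ± 0.24 and 1.60 ± 0.17, and Coro1a, an actin regulator of blood cells, at 2.65 ± 0.17, 2.48 ± 0.18 and 1.47 ± 0.15. Between the metastasis after carbon ions and the unirradiated one 9 of 12 fell, with a median of -1.11, and Cd53, a tetraspanin of white blood cells, stood at -1.51 ± 0.08. After gamma rays none of the 12 passed and the median was -0.28. In the irradiated primaries none passed, with medians of 0.10 and 0.31.

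Of 3 measured genes of the Y chromosome, which cells of the male host carry, 2 were higher in each metastasis than in the unirradiated primary. Ddx3y stood at 1.94 ± 0.27, 1.48 ± 0.19 and 1.35 ± 0.33 in the unirradiated, gamma and carbon metastases and Eif2s3y at 2.09 ± 0.38, 1.81 ± 0.45 and 1.84 ± 0.44, while Kdm5d did not pass in any. In the irradiated primaries Ddx3y stood at -0.39 ± 0.15 and -0.40 ± 0.13. Among adipocyte markers, Cd36 and Lpl, which other cells express too, stood at 4.89 ± 0.06 and 4.63 ± 0.37 in the unirradiated metastasis, and Cfd differed between the metastases after gamma rays and after carbon ions by -4.03 ± 0.22.

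Lung, vessel and blood cell genes were higher in all 3 metastasis RNAs, and RNA of lung tissue in the dissected material is a candidate source: 11 further lung genes, fixed before their values were seen, had medians of at least 1.90, with 9, 10 and 9 of them higher. They also lay above their random range in the primaries after gamma rays and carbon ions, at medians of 0.52 and 0.56 with 1 of 8 and 2 of 9 higher. A higher median of this list therefore need not mean lung tissue, and the reason for it in primaries was not tested. The lists did not rise by the same ratio: the upper quartile of fibroblast genes reached 1.19 at most where the lower quartile of lung genes was at least 2.53. This cannot decide whether a lower share of tumour cells raised every other cell type alike. The ratio of a list depends on how much of that cell type the unirradiated primary already held. Markers of several other cell types were higher together, but the test of expression by the tumour cells alone could not decide. To argue against it, medians of at least 1 were required in 4 lists of other cell types. They had to hold beyond technical error (SD 0.13 for the lowest) and under every alternative, which they did not. Vessel, T cell, B cell and red blood cell genes had medians of at least 1.03 in every metastasis under the chosen settings. All 12 general white blood cell genes rose in the unirradiated and gamma metastases, and 7 rose after carbon ions. The red blood cell median was as low as 0.093 (carbon metastasis) with no filter on dim probes. That setting adds probes that were not well above background in either RNA on both arrays. Host cells that grow into the metastasis and lung tissue taken along at dissection may each contribute, and how much the site changes the tumour cells was not tested.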
